A study of Mus musculus with 58 samples.

How the data were processed

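The 50 bulk libraries were used as the deposited raw counts per gene, whole numbers with a different total in each library. The 8 single-cell libraries were deposited as estimated transcripts per gene and well, a unit other than raw counts: values followed the negative of 256 times ln(1 - n/256) for whole numbers n of molecular identifiers, apart from a highest value of 1597, above what a whole n can give. Tests and thinning used these estimates rounded to whole transcripts, and n itself was used as an alternative. Per the submitters' processing notes, reads were aligned with BWA 0.6.2-r126 to mm10; the counting program, annotation and filters were not stated. Per the labels, the libraries were CEL-seq libraries from Bl/6 mice. Gene positions were taken from GENCODE M21. Some replicate numbers in the names of the sorted libraries differed from those in the titles, which left the groups as they were. Whole-series tables that repeat the sorted and control counts were not used.

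Bulk libraries were fitted in 3 sets (6 h, 96 h, sorted cells with control organoids) with edgeR 4.0.16, using filterByExpr, TMM scaling and the quasi-likelihood test (glmQLFit, glmQLFTest), in R 4.3.3. p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05, and every adjusted p for a gene comes from this test. Sorted Lgr5+ libraries of both lines were compared by the mean of the responses of each line. Gene lists were tested with limma 3.58.1, by camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, and by fry. DESeq2 1.42.0 gave the alternative counts. Of the 22 bulk comparisons, none set 6 h against 96 h, since time and numbered library set coincide.

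In single-cell libraries, wells with at least 1500 transcripts were kept (396 cells). Cells were clustered on 1000 variable genes, 20 principal components and 15 neighbours with the Leiden method at resolution 1, in scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. A cluster took the name of the cell type with the most markers among its top 10 genes, with no tie, by short marker lists that differ from the gene lists tested, where at least 3 markers of that type were 2-fold or more above the other cells, and 22 cells stayed unnamed. The enterocyte-like, the stem-like and 1 of the EEC-like clusters had 2 markers in their top 10. The goblet-like cluster had 3 goblet and 2 Paneth markers there, and further Paneth genes outside the short list, so goblet and Paneth cells were not separated. Shares of cells with a transcript were taken after thinning each cell to 1500 transcripts, with exact binomial intervals, and a leading hormone needed at least 5 transcripts. IDM and IDE cells were summed per library and tested with edgeR as above, and shares per library were compared by an exact permutation test. The ENR and Ei single-cell libraries had no replicates and were compared by counting intervals.

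Genes were named by a fixed rule. Lgr5, Mki67, Chga, Neurog3, Muc2, Lyz1, Dclk1 and Alpi were followed wherever tested. For a described list, up to 4 members with the smallest adjusted p were eligible, and for each main comparison up to 5 rises and 5 falls of largest size among genes past the threshold with at least 20 CPM in the higher group and no overlap between libraries (up to 3 each way elsewhere). In single cells the hormone list was eligible. Comparisons, lists, this rule and the alternatives were chosen before the data were examined, except for 2 alternatives added later: thinning of the 96 h libraries to equal totals, and the sorted set without Ptma.

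Replicate libraries correlated across genes with r from 0.94 to 0.976 at 6 h, from 0.829 to 0.977 at 96 h and from 0.794 to 0.965 in the sorted set. A fold against a group with 0 counts is a lower bound, computed against 3 counts over the group, and where a group held 1 to 3 counts the count ratio is given with its 95% interval. These intervals and bounds cover counting error only. Where leaving out a library left a group with 1 library, that library was assumed to vary like the other groups. Not every list was described for every comparison: those with a result of interest to the question were given. Results for some genes are not reported here.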

Results

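Gene expression was measured by CEL-seq, a 3' end-counting method, in mouse small-intestinal organoids and in cells sorted from them. Whole organoids made up 36 libraries, with 18 at 6 h and 18 at 96 h of treatment and 3 libraries in each of 6 groups per time. The groups were the standard medium with EGF, Noggin and R-spondin (ENR), ENR with an EGFR inhibitor (Ei), ENR with a Mek inhibitor (Mi), combined Wnt and Notch inhibition (ID), and ID with the EGFR inhibitor (IDE) or the Mek inhibitor (IDM). A further 14 libraries held 2 each of Lgr5+ cells from Lgr5-GFP organoids, Lgr5+ cells from Lgr5-DTR organoids and Dclk1+ cells from Dclk1-GFP organoids, in ENR and in Ei, and 2 whole ENR organoid controls. Another 8 libraries held single cells, with 4 of IDE, 2 of IDM, and 1 each of ENR and Ei. Total counts per library ran from 448292 to 2763423 at 6 h (median 1183657), from 158135 to 1738425 at 96 h, and from 668893 to 3599554 in the sorted set. At 96 h the Ei libraries held from 158135 to 554681 counts and the IDM libraries from 231990 to 337789. The 8 genes followed in every comparison, on mm10 (GRCm38), were Lgr5 (ENSMUSG00000020140.15, chromosome 10, 115450311 to 115587780), Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361), Chga (ENSMUSG00000021194.6, chromosome 12, 102554969 to 102565028), Neurog3 (ENSMUSG00000044312.4, chromosome 10, 62133090 to 62134763), Muc2 (ENSMUSG00000025515.15, chromosome 7, 141690340 to 141754693), Lyz1 (ENSMUSG00000069515.6, chromosome 10, 117287797 to 117292868), Dclk1 (ENSMUSG00000027797.15, chromosome 3, 55242364 to 55539068) and Alpi (ENSMUSG00000079440.2, chromosome 1, 87098002 to 87101606). All 8 are annotated as protein-coding genes. They mark stem cells, dividing cells, enteroendocrine cells, enteroendocrine progenitors, goblet cells, Paneth cells, tuft cells and enterocytes, in that order. Levels are given as CPM, counts scaled to a common library size of 1e6 after TMM scaling, given as mean and SD over the libraries of a group, and log2 changes carry their standard error (SE).

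The first question was what EGFR inhibition changes within 6 h in standard medium. Ccnd2, a D-type cyclin that drives entry into S phase, fell 8.71-fold, from 840 CPM (SD 85.6, n = 3) to 97.0 CPM (SD 22.8, n = 3, log2 change -3.12, SE 0.17, adjusted p = 1.1e-16). Genes induced by ERK signalling fell with it, among them Ccnd1 by 3.99-fold, Phlda1 by 4.29-fold, Dusp6 by 4.35-fold and Myc by 3.57-fold. Of 11 genes that restrain division, 5 rose, including Btg2 by 4.22-fold, from 43.8 CPM (SD 0.824) to 185 CPM (SD 15.5), and Btg1 by 2.36-fold. Another of them, the cell cycle inhibitor Cdkn1a, fell 1.63-fold. Adjusted over the list alone 6 of the 11 passed, and the list as a whole was higher (camera adjusted p = 0.00028, and adjusted p = 0.023 with an estimated correlation). The Paneth gene Lyz1 had risen 1.75-fold, from 807 CPM (SD 117) to 1413 CPM (SD 142, adjusted p = 1.6e-04), and the goblet gene Muc2 1.57-fold (adjusted p = 0.0023; 0.077 without Ei replicate 2). Mki67 was at 292 CPM (SD 42.9) against 318 CPM (SD 48.6, log2 change -0.12, adjusted p = 0.54), Lgr5 had a log2 change of -0.28 (adjusted p = 0.27) and Chga one of 0.34 (adjusted p = 0.31), and none of these 3 passed the test. Neurog3, Dclk1 and Alpi did not pass it either. In all, 2638 of 9380 tested genes passed, 1245 higher and 1393 lower in Ei.

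At 6 h of EGFR inhibition Edn1, which encodes endothelin 1, also rose 10.7-fold, Trp53inp1 rose 8.25-fold, and Cyp26b1, which encodes a retinoic acid-degrading enzyme, fell 17.0-fold. 8430408G22Rik rose from 0.485 CPM to 40.5 CPM, a count ratio of 73.1 (95% interval 19.8 to 610), and Cyp1a1, a target of the aryl hydrocarbon receptor, rose from 0.243 CPM to 21.3 CPM, a count ratio of 81.3 (14.2 to 3255). By gene list, 12 of 15 tested ERK target genes fell (13 adjusted over the list alone), with a median log2 change of -1.84 (camera adjusted p = 4.2e-10, and adjusted p = 0.00065 with an estimated correlation). Of 23 S phase genes 18 fell (21 adjusted over the list alone, median -0.91, camera adjusted p = 3e-14, and adjusted p = 0.00023 with an estimated correlation), with Ung down 5.71-fold. Ribosome biogenesis genes fell in 16 of 17 cases (17 adjusted over the list alone, median -1.53, camera adjusted p = 8e-21, and adjusted p = 7.2e-05 with an estimated correlation). The 23 G2/M genes had a median of -0.10, with 2 higher and 2 lower (camera adjusted p = 0.86). All 17 tested Paneth genes rose (17 adjusted over the list alone, median 0.96, camera adjusted p = 1.8e-10), a list result that ended with an estimated correlation (adjusted p = 0.072 with an estimated correlation). Goblet markers rose in 10 of 13 cases and fell in 1 (12 adjusted over the list alone, camera adjusted p = 3.6e-05, and adjusted p = 0.047 with an estimated correlation).

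Mek inhibition for 6 h asked whether blocking the pathway below EGFR gives the same response. Ccnd2 fell 8.56-fold to 98.0 CPM (SD 18.4, n = 3, log2 change -3.10, SE 0.17, adjusted p = 1.1e-16). The ERK feedback phosphatase Dusp6 fell 10.6-fold and the immediate early gene Egr1 12.3-fold, while the antimicrobial lectin Reg3g rose 6.21-fold. Lyz1 rose 1.47-fold (adjusted p = 0.0088; 0.10 at most when ENR replicate 1 or Mi replicate 2 was left out), and Mki67, Lgr5 and Chga did not pass the test (adjusted p = 0.63, 0.31 and 0.37). The test passed 2166 genes, 958 higher and 1208 lower. S phase genes fell in 21 of 23 cases (21 adjusted over the list alone, median -1.20, camera adjusted p = 1.7e-18, and adjusted p = 6.2e-05 with an estimated correlation), and cholesterol synthesis genes in 14 of 18 (16 adjusted over the list alone, median -0.85, camera adjusted p = 7.2e-12, and adjusted p = 0.004 with an estimated correlation). Paneth genes rose in 8 of 17 cases (11 adjusted over the list alone, camera adjusted p = 4.7e-05, but adjusted p = 0.28 with an estimated correlation).

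Set directly against each other at 6 h, the inhibitors differed in 9 genes (713 at an unadjusted p under 0.05). Cyp1a1 was 5.99-fold lower in Mi than in Ei (log2 change -2.58, SE 0.42, adjusted p = 0.0018; 0.051 without Mi replicate 3), and 8430408G22Rik was 5.15-fold lower (adjusted p = 2.4e-04). Ccnd1 was the 1 gene higher in Mi (1.71-fold, adjusted p = 0.031), a call that ended in 5 of the 6 fits with 1 library left out (adjusted p up to 0.24). The other 6 genes, all lower in Mi, were Mt4 (adjusted p = 0.12 without Mi replicate 3), Dhcr7 (lost in 5 of the 6 such fits, up to 0.35), Gclc, Gsta2, Scd2 and Srxn1, the last 4 of which were named after their values were seen. The count was 21 without Ei replicate 2, 4 without Mi replicate 2 and 1 without Mi replicate 3.

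Wnt and Notch inhibition for 6 h, by contrast, moved 21 genes (7 higher, 14 lower; 805 at an unadjusted p under 0.05), with Wnt targets among those that fell. Sox9 fell 2.68-fold, from 293 CPM (SD 28.8, n = 3) to 110 CPM (SD 10.8, n = 3, log2 change -1.42, SE 0.16, adjusted p = 1.7e-06). Ephb3 fell 2.54-fold (adjusted p = 1.1e-05), and the stem-cell transcription factor Ascl2 1.81-fold (adjusted p = 0.0056; up to 0.085 without ENR replicate 3 or ID replicate 3). Lgr5 itself was at 70.5 CPM (SD 10.7) against 81.9 CPM (SD 16.8), which did not pass (adjusted p = 0.89). Wnt target genes fell in 5 of 12 cases (6 adjusted over the list alone, median -0.68, camera adjusted p = 6.9e-16, and adjusted p = 5.3e-05 with an estimated correlation). The drug-metabolising gene Cyp2c55 rose 2.37-fold (adjusted p = 0.0012). With no low-count filter 26 were higher and 30 lower. The count was 10 without ENR replicate 2, 5 without ENR replicate 3 and 5 without ID replicate 3. ID and ENR libraries belong to different numbered library sets, so treatment and set cannot be told apart here or at 96 h.

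The next comparisons added each inhibitor to ID for 6 h. EGFR inhibition lowered Dusp6 7.65-fold, from 40.3 CPM (SD 6.35, n = 3) to 5.23 CPM (SD 2.54, n = 3, log2 change -2.94, SE 0.30, adjusted p = 1.8e-09), and Phlda1 4.84-fold. Mek inhibition lowered Ccnd2 10.5-fold, from 562 CPM (SD 62.3) to 53.2 CPM (SD 6.66), and Dusp6 13.1-fold, and raised Lyz1 1.62-fold (adjusted p = 0.0013). The enteroendocrine regulator Neurog3 rose in IDE, from 44.8 CPM (SD 6.45) to 65.9 CPM (SD 8.41, adjusted p = 0.029), a call that ended without ID replicate 2, ID replicate 3, IDE replicate 1 or IDE replicate 2 (up to 0.18). Mki67 and Chga passed in neither comparison. ERK target genes fell in 12 of 15 cases in both (13 adjusted over the list alone, median -1.84 in IDE and -2.01 in IDM, adjusted p = 0.0002 and 0.00017 with an estimated correlation). S phase genes fell in 20 and 17 of 23 (20 and 19 adjusted over the list alone, adjusted p = 7.6e-05 and 0.00013 with an estimated correlation). The counts were 2109 genes for IDE against ID (935 higher, 1174 lower) and 1938 for IDM against ID (911 higher, 1027 lower). IDM and IDE differed in 2 genes (893 at an unadjusted p under 0.05): 2210407C18Rik was 1.79-fold higher and Scd2, a fatty acid desaturase, 1.81-fold lower in IDM (both adjusted p = 0.0043; 0.12 without IDE replicate 2 or IDM replicate 2). That count was 5 without IDE replicate 1, 0 without IDE replicate 2, 4 without IDM replicate 1, 0 without IDM replicate 2 and 14 without IDM replicate 3.

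After 96 h of EGFR inhibition the comparison addressed which cell type markers are higher and lower than in ENR. The enteroendocrine granule protein gene Chga rose 14.1-fold, from 27.3 CPM (SD 2.84, n = 3) to 383 CPM (SD 108, n = 3, log2 change 3.81, SE 0.24, adjusted p = 1.1e-13). Lyz1 rose 10.4-fold, to 12579 CPM (SD 2170, adjusted p = 5.5e-14), Muc2 5.17-fold to 841 CPM (SD 222) and Dclk1 4.59-fold to 62.8 CPM (SD 18.4). Neurog3 rose 2.29-fold, to 95.8 CPM (SD 24.3, adjusted p = 0.0065). Mki67 fell 2.96-fold, from 269 CPM (SD 49.4) to 93.9 CPM (SD 11.5, adjusted p = 1e-04), and the enterocyte phosphatase gene Alpi 2.40-fold. Lgr5 was at 113 CPM (SD 7.49) against 155 CPM (SD 11.4), a difference that did not pass the test (log2 change -0.47, SE 0.21, adjusted p = 0.11) although the libraries of both groups did not overlap. The test passed 1495 of 8135 genes, 769 higher and 726 lower, and 948 without Ei replicate 1.

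All 17 tested Paneth genes rose at 96 h of EGFR inhibition (17 adjusted over the list alone, median log2 change 4.23, camera adjusted p = 1.4e-47, and adjusted p = 3.3e-04 with an estimated correlation), led by the defensin Defa22, up 31.7-fold, and Mptx2, up 55.6-fold. All 14 genes of the enteroendocrine secretory machinery rose (14 adjusted over the list alone, median 2.83, camera adjusted p = 1.8e-16, and adjusted p = 3.3e-04 with an estimated correlation), including Chgb, from 272 CPM (SD 49.7) to 2171 CPM (SD 114). Hormone genes rose in 5 of 9 cases (6 adjusted over the list alone, median 2.53, camera adjusted p = 6.4e-09, and adjusted p = 0.0087 with an estimated correlation), with Gip at 251 CPM (SD 14.6) against 21.0 CPM (SD 4.41). Tuft genes rose in 6 of 7 cases (7 adjusted over the list alone) and goblet genes in 9 of 13 (10 adjusted over the list alone). G2/M genes fell in 17 of 21 cases (20 adjusted over the list alone, median -1.51, camera adjusted p = 1.1e-12, and adjusted p = 0.0049 with an estimated correlation), and cholesterol synthesis genes in 16 of 17 (16 adjusted over the list alone, median -1.50, camera adjusted p = 4.2e-15, and adjusted p = 3.3e-04 with an estimated correlation). Of 15 tested stem cell markers 1 was higher and 2 lower (3 adjusted over the list alone, median 0.07, mean -0.17, camera adjusted p = 0.53). The antimicrobial gene Reg3b (ENSMUSG00000071356.7, chromosome 6, 78370657 to 78373466) was undetected in ENR and at least 93.7-fold higher in Ei, at 61.6 CPM (SD 12.9).

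**Figure D1:**
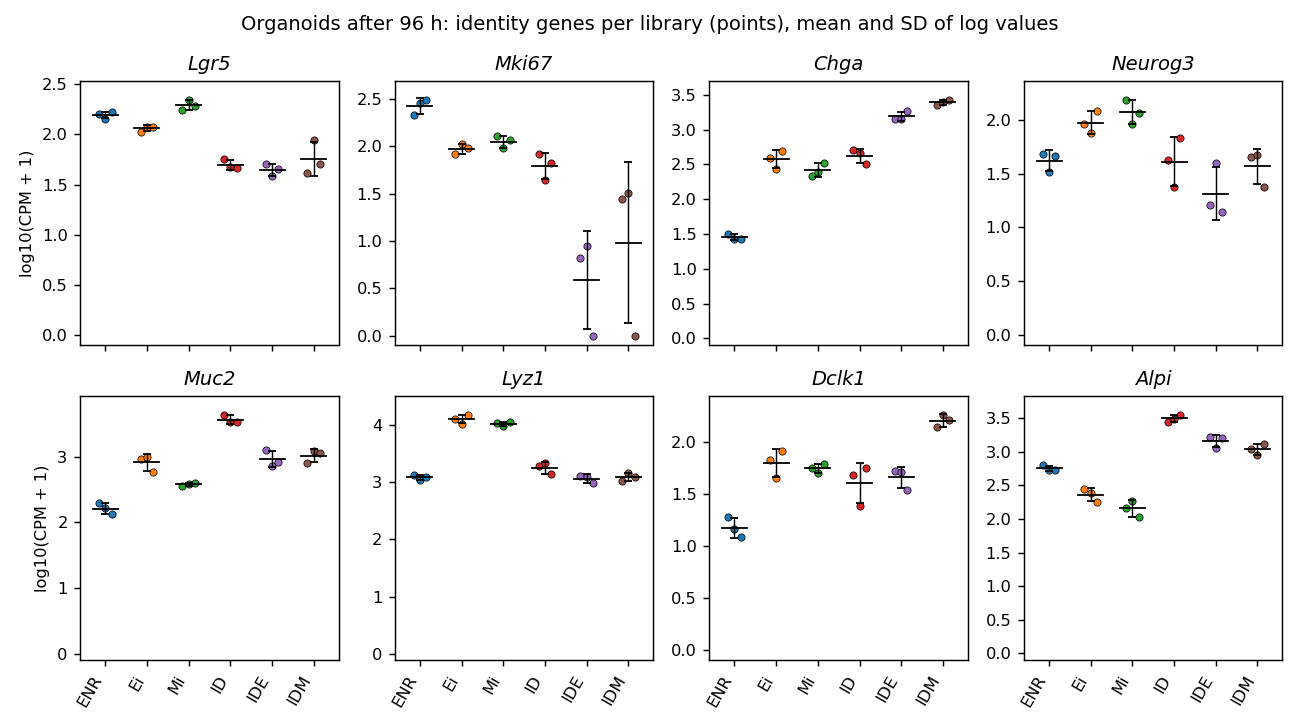
Levels of the 8 identity genes in the 18 organoid libraries at 96 h, as log10 of CPM plus 1; points are libraries, and bars are the mean and SD of the log values of 3 libraries. Chga averaged 27.3 CPM in ENR and 2466 CPM in IDM, and Lyz1 1209 CPM in ENR and 12579 CPM in Ei.

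Mek inhibition for 96 h was compared with ENR in the same way. Chga rose 9.65-fold to 265 CPM (SD 61.1, n = 3, log2 change 3.27, SE 0.23, adjusted p = 2e-12), Lyz1 rose to 10273 CPM (SD 767) and Dclk1 3.91-fold, while Alpi fell 3.91-fold and Mki67 2.40-fold. Neurog3 rose 2.90-fold, to 121 CPM (SD 31.5), and Muc2 2.33-fold, while the goblet gene Zg16 fell 4.73-fold. Goblet genes as a list did not pass, with 7 of 13 higher and 3 lower (11 adjusted over the list alone, camera adjusted p = 0.052). Lgr5 was at 194 CPM (SD 23.3) against 155 CPM (SD 11.4), which did not pass (adjusted p = 0.18). Thrombospondin 1 (Thbs1) rose 45.1-fold and Reg3b at least 103-fold, and the hypoxia-inducible gene Egln3 fell 30.4-fold, from 615 CPM (SD 92.1) to 19.8 CPM (SD 5.08). In total 1894 genes passed, 933 higher and 961 lower. Paneth genes rose in 17 of 17 cases (17 adjusted over the list alone, median 3.47, adjusted p = 0.0011 with an estimated correlation), enteroendocrine transcription factors in 8 of 11 (10 adjusted over the list alone, adjusted p = 0.0011 with an estimated correlation), and hormones in 5 of 9 (5 adjusted over the list alone, camera adjusted p = 8.4e-04, but adjusted p = 0.11 with an estimated correlation).

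Between the inhibitors at 96 h, 88 genes differed, 81 of them lower in Mi (808 at an unadjusted p under 0.05). Among goblet genes, Zg16 was 9.19-fold lower in Mi, at 24.6 CPM (SD 6.06, n = 3) against 229 CPM (SD 10.9, n = 3, log2 change -3.20, SE 0.33, adjusted p = 2.9e-07), Clca1 8.82-fold lower and Muc2 2.22-fold lower (adjusted p = 0.0024). Msln, which encodes mesothelin, was 16.3-fold lower, Gip 2.11-fold lower (adjusted p = 0.001) and Lgr5 1.74-fold higher without passing (adjusted p = 0.053). Stem cell markers as a list were higher in Mi, with 0 of 15 called (6 adjusted over the list alone, median 0.52, camera adjusted p = 1.8e-06, and adjusted p = 0.018 with an estimated correlation). Paneth genes were lower in 7 of 17 cases (11 adjusted over the list alone, median -0.85, adjusted p = 0.018 with an estimated correlation) and goblet genes in 5 of 13 (6 adjusted over the list alone, adjusted p = 0.018 with an estimated correlation). The count was 58 without Ei replicate 3, 56 without Mi replicate 2 and 58 without Mi replicate 3, and 53 when only the 6 libraries compared were fitted.

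Wnt and Notch inhibition for 96 h addressed differentiation without the stem cell signals. Muc2 rose 22.7-fold, from 163 CPM (SD 31.8, n = 3) to 3698 CPM (SD 572, n = 3, SE of the log2 change 0.24, adjusted p = 1.8e-15), and the goblet lectin Zg16 121-fold, to 14226 CPM (SD 5302). Alpi rose 5.49-fold to 3129 CPM (SD 371), the lipid carrier Apoa1 23.2-fold, Chga 15.5-fold to 426 CPM (SD 91.5), and Dclk1 3.11-fold. Lgr5 fell 3.13-fold, to 48.9 CPM (SD 5.82), Mki67 4.10-fold, and the Notch target Hes1 2.18-fold. Lyz1 rose 1.49-fold (adjusted p = 0.017), a call that ended without ENR replicate 2, ID replicate 1 or ID replicate 2 (up to 0.11), and Neurog3 did not pass (adjusted p = 0.74). In total 3097 genes passed, 1605 higher and 1492 lower. Enterocyte genes rose in 20 of 21 cases (20 adjusted over the list alone, median 2.77, adjusted p = 0.003 with an estimated correlation), hormones in 9 of 9 (9 adjusted over the list alone, median 3.62, adjusted p = 0.0069 with an estimated correlation), and stem cell markers fell in 14 of 15 (14 adjusted over the list alone, median -1.62, adjusted p = 0.0069 with an estimated correlation). Interferon response genes also rose, with 6 of 7 higher and Ifitm3 lower (7 adjusted over the list alone, median 5.19, camera adjusted p = 1.1e-04, and adjusted p = 0.035 with an estimated correlation). Ifit1 went from 7.12 CPM (SD 1.87) to 380 CPM (SD 142).

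Adding EGFR inhibition to Wnt and Notch inhibition asked which markers the inhibitor changes there. Chga rose 3.65-fold over ID, to 1554 CPM (SD 232, n = 3, log2 change 1.87, SE 0.20, adjusted p = 2.5e-08), Gip 2.68-fold to 852 CPM (SD 105) and Sst 2.21-fold to 552 CPM (SD 33.7). Tph1, which makes serotonin, rose 1.71-fold (adjusted p = 0.016; up to 0.14 without ID replicate 3 or IDE replicate 3), while Cck fell 2.17-fold to 244 CPM (SD 91.2, adjusted p = 0.0011). Muc2 fell 3.95-fold, Alpi 2.16-fold and Mki67 11.3-fold, to 4.53 CPM (SD 4.08), and Lyz1 1.55-fold (adjusted p = 0.014; up to 0.089 without ID replicate 2 or IDE replicate 3). The log2 change of Mki67 was -3.50, and -4.23 without IDE replicate 2. Dclk1, Lgr5 and Neurog3 did not pass (adjusted p = 0.87, 0.61 and 0.10). The haem oxygenase gene Hmox1 rose 17.3-fold and the metallothionein Mt4 15.8-fold, whereas adenosine deaminase (Ada) was undetected in IDE and at least 75.6-fold lower. In total 1939 genes passed, 875 higher and 1064 lower. Hormones rose in 3 of 9 cases and fell in 1 (4 adjusted over the list alone, camera adjusted p = 0.042, but adjusted p = 0.28 with an estimated correlation). G2/M genes fell in 17 of 21 cases (19 adjusted over the list alone, median -2.82, adjusted p = 0.03 with an estimated correlation).

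Mek inhibition on top of ID raised Chga 5.80-fold, to 2466 CPM (SD 182, n = 3, log2 change 2.54, SE 0.20, adjusted p = 1.1e-10), Chgb 3.21-fold to 8125 CPM (SD 241), Gip 3.39-fold to 1080 CPM (SD 91.6) and Tph1 2.83-fold to 485 CPM (SD 110). Dclk1 rose 3.67-fold, to 159 CPM (SD 21.7), and the tuft cell channel gene Trpm5 9.90-fold. The goblet genes Clca1 and Zg16 fell 117-fold and 30.5-fold, Muc2 3.50-fold and Alpi 2.85-fold, while Ccl6 of the goblet list rose 5.4-fold. In that list 7 of 13 genes fell and 1 rose (9 adjusted over the list alone, median -1.04, adjusted p = 0.024 with an estimated correlation). Mki67 fell 3.32-fold (adjusted p = 0.0086, and 0.064 without IDM replicate 3), and Lgr5, Lyz1 and Neurog3 did not pass (adjusted p = 0.55, 0.06 and 0.73). The log2 change of Mki67 was -1.73, with -1.16 without IDM replicate 3 and -2.38 without IDM replicate 2. In total 1100 genes passed, 437 higher and 663 lower, and 719 without IDM replicate 2. The enteroendocrine secretory machinery rose in 9 of 14 cases (11 adjusted over the list alone, median 1.33, adjusted p = 0.0026 with an estimated correlation) and tuft genes in 6 of 7 (6 adjusted over the list alone, median 2.52, adjusted p = 0.0093 with an estimated correlation). Hormones rose in 4 of 9 cases and fell in 1 (9 adjusted over the list alone, camera adjusted p = 0.0066, but adjusted p = 0.18 with an estimated correlation).

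IDM and IDE differed at 96 h in 382 genes, 173 higher and 209 lower in IDM. This balance reversed when only the groups compared were fitted (408 genes, 268 higher and 140 lower). Dclk1 was 3.45-fold higher in IDM (log2 change 1.79, SE 0.26, n = 3 per group, adjusted p = 4.3e-05), Ptprn, a granule membrane gene, 3.25-fold higher (adjusted p = 0.0029) and Chgb 1.89-fold higher (adjusted p = 0.0046). Hmox1 was lower, at 19 CPM (SD 9.1) against 398 CPM (SD 80), and Zg16 6.08-fold lower. Chga was 1.59-fold higher (adjusted p = 0.039), a call that ended in 5 of the 6 fits with 1 library left out, all but that without IDE replicate 3 (up to 0.12). Enteroendocrine transcription factors as a list were higher in IDM, with 1 of 11 called (4 adjusted over the list alone, camera adjusted p = 2.3e-04, and adjusted p = 0.019 with an estimated correlation). The count was 212 without IDE replicate 2, 201 without IDE replicate 3 and 105 without IDM replicate 2.

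**Figure D2:**
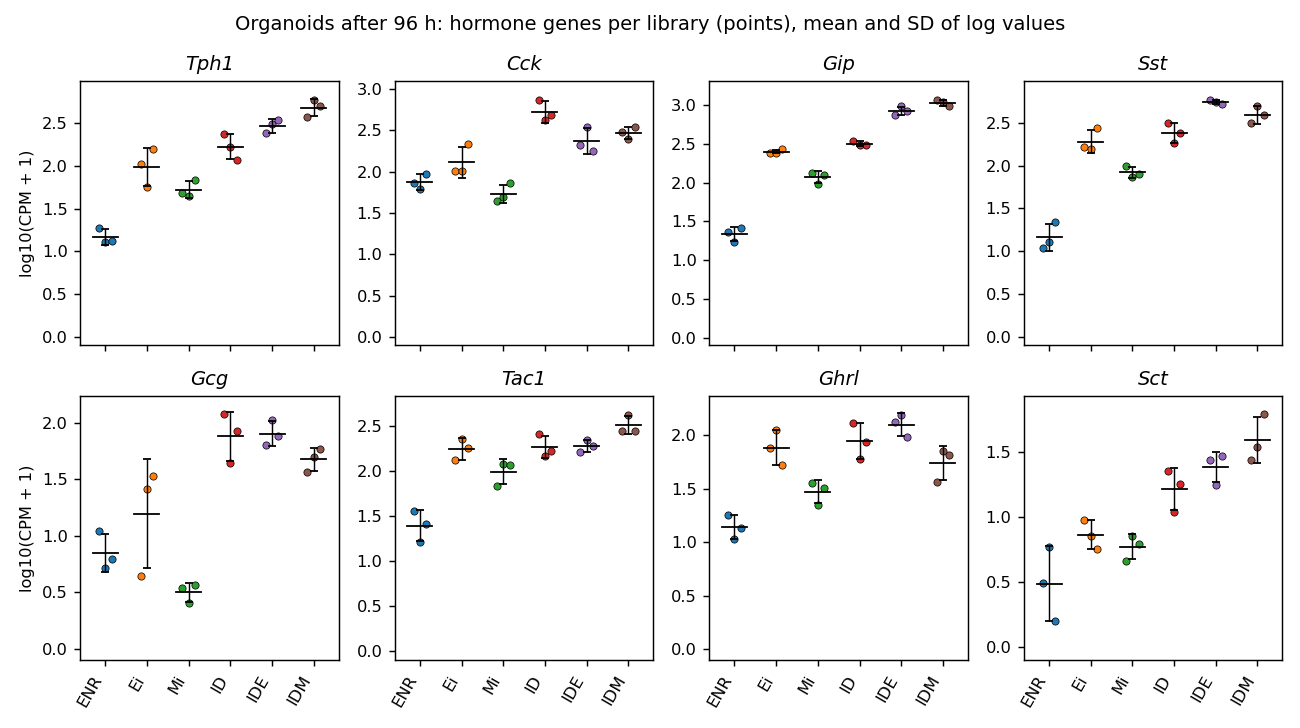
Levels of 8 hormone genes in the 18 organoid libraries at 96 h, as log10 of CPM plus 1; points are libraries, and bars are the mean and SD of the log values of 3 libraries. Gip averaged 21.0 CPM in ENR, 251 CPM in Ei, 852 CPM in IDE and 1080 CPM in IDM, and Cck 540 CPM in ID and 244 CPM in IDE.

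The difference of the responses was tested directly at 96 h, to see which effects of each inhibitor depend on Wnt and Notch signals. Lyz1 rose 10.4-fold under EGFR inhibition in ENR and fell 1.55-fold in ID, a difference of responses of log2 -4.02 (SE 0.28, n = 3 per group, adjusted p = 7e-12). For Muc2 the difference was -4.35 (adjusted p = 1.4e-11), for Chga -1.95 (adjusted p = 2.6e-05), for Dclk1 -2.11 (adjusted p = 6.7e-04) and for Neurog3 -2.06 (adjusted p = 0.0042). Muc2, like Lyz1, rose in ENR and fell in ID. Chga rose in both, from a higher level in ID, so its difference is a smaller fold rise there and not a lost response. Mki67 differed by -1.93 (adjusted p = 0.023, and up to 0.072 without ID replicate 1 or IDE replicate 3), and Lgr5 and Alpi did not differ detectably (adjusted p = 0.67 and 0.80). Without IDE replicate 2 the differences were larger, at -2.83 for Neurog3 and -2.62 for Mki67. For Mek inhibition Lyz1 differed by -3.63 (adjusted p = 1.5e-10) and Muc2 by -3.03 (adjusted p = 2.4e-08). Neurog3 differed by -1.82 (adjusted p = 0.023; up to 0.16 without ENR replicate 2, Mi replicate 1, ID replicate 3 or IDM replicate 3), and Chga did not pass (-0.73, adjusted p = 0.15). The counts were 1149 genes for EGFR inhibition (511 with a higher and 638 with a lower response in ID) and 472 for Mek inhibition (191 and 281). Both balances depended on the processing: with no low-count filter 691 were higher and 522 lower for EGFR inhibition. With DESeq2 50.9% of 503 genes were higher for Mek inhibition. Every one of 17 Paneth genes had a lower response to EGFR inhibition in ID (17 adjusted over the list alone, median -4.25, adjusted p = 0.0032 with an estimated correlation), and so did 12 of 13 goblet genes (12 adjusted over the list alone, adjusted p = 0.0032 with an estimated correlation).

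**Figure D3:**
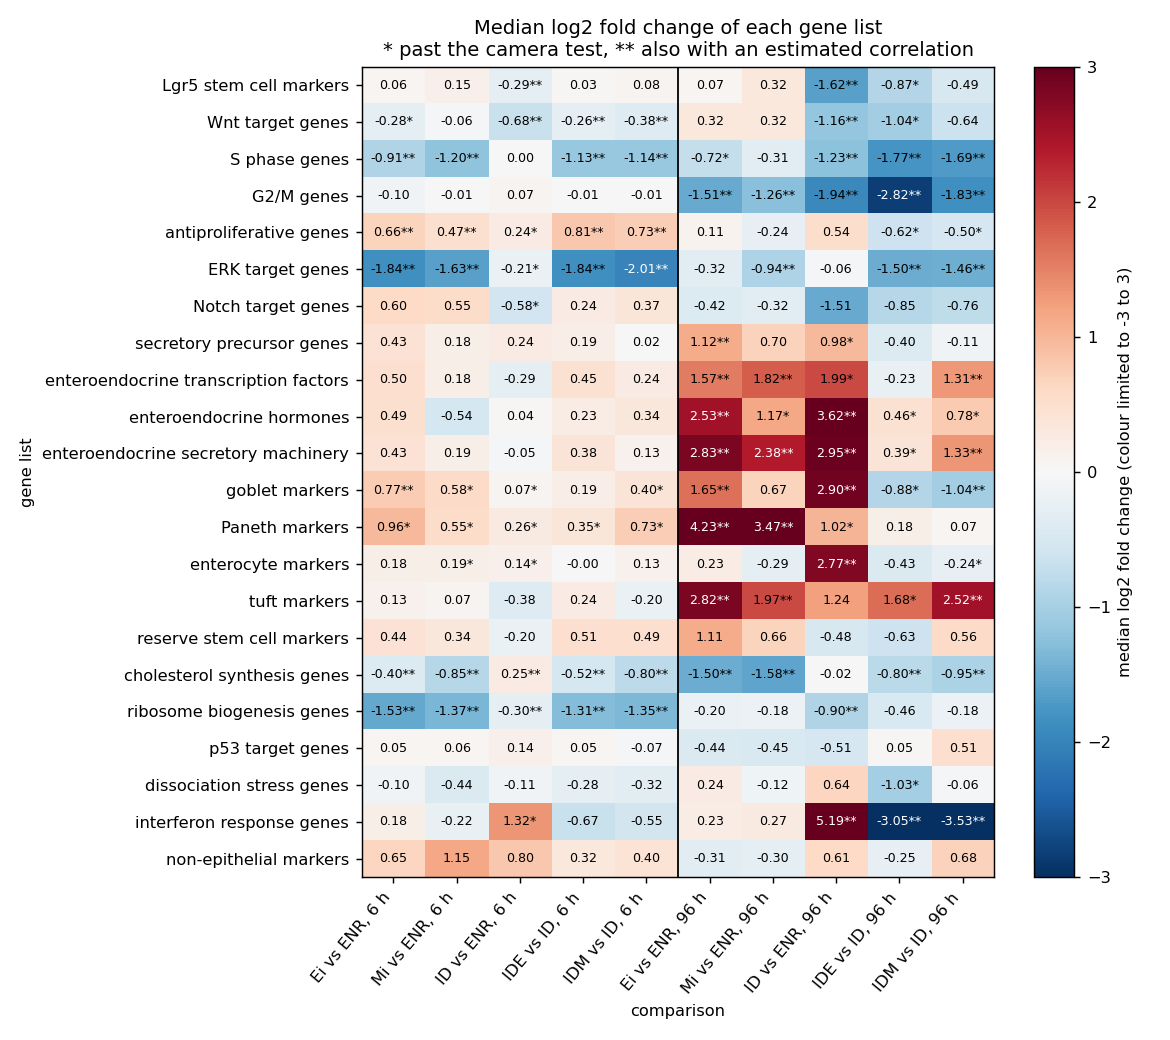
Median log2 change of each gene list in 10 organoid comparisons, printed in each cell, with colour limited to 3 either way; 1 star marks a list past the camera test and 2 stars a list also past it with an estimated correlation. The Paneth list stood at 4.23 in Ei against ENR at 96 h, and the ERK target list at -1.84 in Ei against ENR at 6 h.

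Lgr5+ cells sorted from EGFR-inhibited organoids were compared with those from ENR organoids, 4 libraries per treatment from 2 mouse lines, to describe stem cells under the inhibitor. Dclk1, a tuft cell marker, rose 5.90-fold (log2 change 2.56, SE 0.32, n = 4 per treatment, adjusted p = 1.3e-04), from 3.63 CPM (SD 0.870, n = 2) to 22.5 CPM (SD 8.44, n = 2) in Lgr5-GFP cells and from 8.27 CPM (SD 2.76) to 47.9 CPM (SD 13.9) in Lgr5-DTR cells. The tuft gene Avil rose 2.95-fold and Trpm5 2.73-fold (adjusted p = 0.0095; up to 0.075 without Lgr5-GFP Ei replicate 1, Lgr5-GFP ENR replicate 1 or Lgr5-DTR ENR replicate 2). The brush-border gene Anpep rose 6.51-fold, and Hbegf, an EGFR ligand, 3.24-fold. Etv4, an ERK-dependent transcription factor, fell 8.19-fold, the homeobox gene Isx 12.7-fold and the sterol enzyme Lss 4.23-fold. Reg3b rose in both lines, from 1.06 CPM and 0 CPM to 83.3 CPM (SD 42.7) and 19.3 CPM (SD 2.83), a count ratio of 92.8 (95% interval 31.4 to 452). Lgr5 (log2 change 0.96, adjusted p = 0.14) and Mki67 (-1.15, adjusted p = 0.12) did not pass, nor did Chga, Neurog3, Muc2, Lyz1 or Alpi.

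In these Lgr5+ cells 510 of 10325 genes passed, 297 higher and 213 lower in Ei. The count was higher with only the groups compared and with no low-count filter. Leaving out any 1 of the 8 libraries gave a lower count: 286 and 295 without Lgr5-GFP Ei replicates 1 and 2, 268 and 261 without Lgr5-GFP ENR replicates 1 and 2, 286 and 270 without Lgr5-DTR Ei replicates 1 and 2, and 274 and 233 without Lgr5-DTR ENR replicates 1 and 2. Cholesterol synthesis genes fell in 12 of 18 cases (16 adjusted over the list alone, median -1.09, adjusted p = 0.002 with an estimated correlation). Stem cell markers rose in 4 of 17 cases (5 adjusted over the list alone, median 0.55, adjusted p = 0.03 with an estimated correlation) and enterocyte genes in 7 of 21 (10 adjusted over the list alone, median 1.00, or 0.86 with genes undetected in a group at their bound, adjusted p = 0.022 with an estimated correlation). G2/M genes fell in 4 of 23 cases (14 adjusted over the list alone, median -1.01, adjusted p = 0.042 with an estimated correlation). Tuft genes rose in 7 of 16 cases (11 adjusted over the list alone, median 1.46 with and without the bound, camera adjusted p = 9.2e-06, but adjusted p = 0.08 with an estimated correlation). The response did not differ detectably between the lines: 0 genes passed edgeR's test of the difference, 262 did at an unadjusted p under 0.05, and DESeq2 called 0. For Dclk1 this difference was log2 0.0284 with an SE of 1.1, so sizeable line differences could go unseen.

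**Figure D4:**
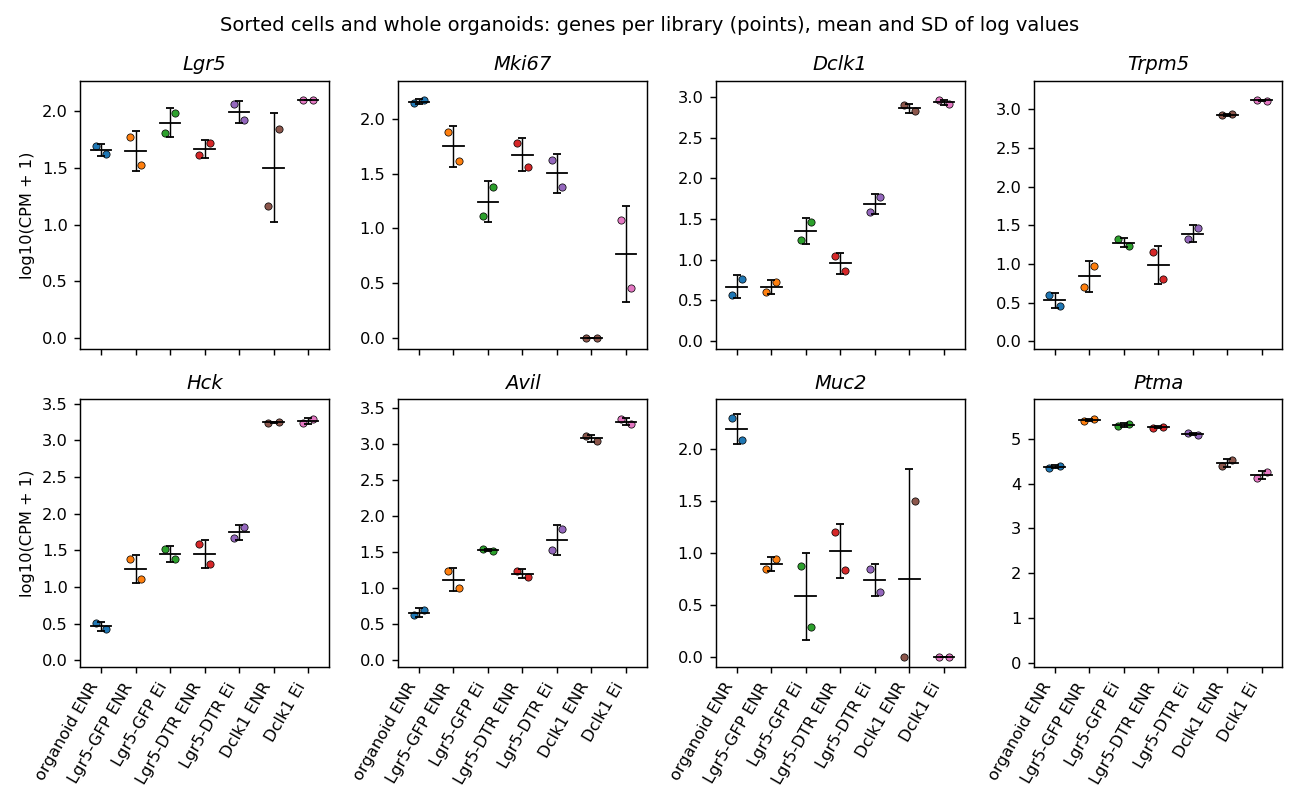
Levels of 8 genes in the 14 sorted and whole-organoid control libraries, as log10 of CPM plus 1; points are libraries, and bars are the mean and SD of the log values of 2 libraries. Dclk1 averaged 3.63 CPM and 8.27 CPM in the Lgr5+ groups in ENR, 22.5 CPM and 47.9 CPM in Ei, and 728 CPM in Dclk1+ cells in ENR.

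In Dclk1+ cells EGFR inhibition left Dclk1 at 866 CPM (SD 63.1, n = 2) against 728 CPM (SD 91.3, n = 2), which did not pass (adjusted p = 0.70). Etv4 fell 13.0-fold, from 19.9 CPM (SD 12.8) to 1.54 CPM (SD 0.445, log2 change -3.70, SE 0.62, adjusted p = 0.0034), and Ak4, an adenylate kinase gene, was undetected in Ei and at least 55.1-fold lower. The peptidase gene Ctso and the sterol transporter gene Abcg5 were undetected in ENR and at least 20.9-fold and 20.3-fold higher in Ei. Goblet genes fell in 4 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.0067, but adjusted p = 0.61 with an estimated correlation), and the ENR libraries were uneven in such transcripts: ENR replicate 2 held 30.6 CPM of Muc2 and 242 CPM of Lyz1, where ENR replicate 1 held 0 CPM and 27.3 CPM. In total 345 genes passed, 114 higher and 231 lower, 703 without ENR replicate 1 and 555 without ENR replicate 2. With only the groups compared 21 passed. The response of Dclk1 was lower in Dclk1+ than in Lgr5+ cells by log2 -2.31 (SE 0.45, adjusted p = 0.023; up to 0.067 without Lgr5-GFP Ei replicate 2, Lgr5-GFP ENR replicate 1 or 2, or Lgr5-DTR ENR replicate 2), and 130 genes differed in response, 42 higher and 88 lower. Enterocyte genes were lower in response, with 4 of 21 called (9 adjusted over the list alone, median -2.98, camera adjusted p = 1.3e-07, and adjusted p = 0.029 with an estimated correlation). In Dclk1+ cells 6 of the 21 members were at 0 in 1 condition. The Dclk1+ ENR libraries were uneven in them, with Alpi at 7.04 CPM (SD 9.96) and Apoa4 at 34 CPM (SD 38.7). That count ranged widely as libraries were left out: 43 and 39 without Lgr5-GFP Ei replicates 1 and 2, 42 and 38 without Lgr5-GFP ENR replicates 1 and 2, 31 and 61 without Lgr5-DTR Ei replicates 1 and 2, 41 and 49 without Lgr5-DTR ENR replicates 1 and 2, and 418 and 360 without Dclk1 ENR replicates 1 and 2.

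Sorted cells were also set against whole organoids in ENR, to see what the sorts enrich. Dclk1+ cells held 191-fold more Dclk1 (728 CPM, SD 91.3, n = 2, against 3.77 CPM, SD 1.53, n = 2, log2 change 7.57, SE 0.43, adjusted p = 1.8e-09), and all 16 tested tuft genes were higher (16 adjusted over the list alone, median 8.38, or 7.97 with the bound, adjusted p = 0.011 with an estimated correlation). Mki67 was undetected in them and at least 92.2-fold lower than in organoids. The immediate early genes Jun and Fosb were 13.8-fold and 24-fold higher in them. The leukocyte marker Ptprc was at 54.4 CPM (SD 40.7) against 0.245 CPM (SD 0.347), a count ratio of 185 (95% interval 49.7 to 1547). Dissociation stress genes were higher in 6 of 10 cases (8 adjusted over the list alone, camera adjusted p = 0.0043, but adjusted p = 0.26 with an estimated correlation). Lgr5+ cells held as much Lgr5 as whole organoids, 45.5 CPM (SD 18.2) and 46.0 CPM (SD 8.34) in the 2 lines against 44.6 CPM (SD 5.51, adjusted p = 0.98). The differentiation genes Alpi, Chga and Muc2 were 18.2-fold, 32.0-fold (adjusted p = 0.067 without Organoid replicate 2) and 19.0-fold lower, and Jun and Fosb 39.1-fold and 52.0-fold higher. Lyz1 was 5.40-fold lower (adjusted p = 0.011, up to 0.062 without Lgr5-GFP ENR replicate 1, Lgr5-DTR ENR replicate 2 or Organoid replicate 2). Mki67 was 2.74-fold lower (adjusted p = 0.039, up to 0.24 without Lgr5-GFP ENR replicate 2 or any Lgr5-DTR ENR or Organoid replicate). The Chga log2 change of -5.00 ran from -7.09 without Lgr5-GFP ENR replicate 2 to -4.38 without Lgr5-DTR ENR replicate 2. Against the direction of Mki67, S phase and G2/M genes as lists were higher in Lgr5+ cells (camera adjusted p = 0.0013 and 3e-05). Neither list passed with an estimated correlation (adjusted p = 0.15 and 0.18). Stem cell markers were higher in 6 of 17 cases (8 adjusted over the list alone, median 0.78, adjusted p = 0.026 with an estimated correlation) and dissociation stress genes in 7 of 10 (9 adjusted over the list alone, median 2.61, adjusted p = 0.035 with an estimated correlation). In total 1239 genes differed for Lgr5+ cells (572 higher, 667 lower) and 3130 for Dclk1+ cells (1363 and 1767). With only the groups compared this order reversed, the Lgr5+ count rising and the Dclk1+ count falling. The Lgr5+ count was 806 without Lgr5-GFP ENR replicate 2, 788 and 771 without Lgr5-DTR ENR replicates 1 and 2, and 592 and 432 without Organoid replicates 1 and 2, and the Dclk1+ count 2044 and 1769 without the latter.

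Single cells asked which cell types the combined inhibitions produce, and whether EGFR-inhibited stem cells still divide. Of 96 wells per library, 23 to 60 in IDE, 21 and 63 in IDM, 74 in ENR and 71 in Ei were kept. Clusters with enteroendocrine markers (EEC-like) held 47.2% of IDE cells (SD 10.5, n = 4 libraries) and 45.2% of IDM cells (SD 37.0, n = 2), a difference of -1.93 points (2-sided exact permutation p = 1, smallest possible 0.067). The IDM libraries were far apart, at 19.0% (4 of 21 cells, exact 95% interval 5.45% to 41.9%) and 71.4% (45 of 63, 58.7% to 82.1%). Among EEC-like cells Tph1 was the leading hormone gene in 31 of 81 IDE cells and 18 of 49 IDM cells, followed in IDE by Cck (13), Sst (12), Gip (11) and Tac1 (9), and in IDM by Tac1 (10) and Gip (8). IDM replicate 2 gave 45 of the 49 IDM cells, among them 17 of the 18 led by Tph1. After thinning to 1500 transcripts, Gip was found in 32.1% of IDE EEC-like cells (interval 22.2% to 43.4%, median depth 3839) against 6.25% (1.31% to 17.2%) of enterocyte-like cells with a median depth of 17091. Gip was among the top 10 genes of an EEC-like cluster, so the clustering itself favoured this difference, which is no separate evidence. These intervals pool the cells of 4 IDE libraries and leave out the spread between libraries. Between IDM and IDE 0 of 5850 genes passed edgeR's test on summed cells (115 at an unadjusted p under 0.05, 0 by DESeq2), with Gcg, which encodes glucagon and GLP-1, at a log2 change of 2.16 (SE 0.47, adjusted p = 0.96), and 6 genes passed without IDM replicate 2. In counts simulated for these libraries, edgeR's test recovered 8% of 2-fold and 63% of 4-fold changes, so many differences could go unseen. The difference in share was 24.3 points without IDM replicate 1, -28.1 without IDM replicate 2 and 2.9 without IDE replicate 1. Enteroendocrine machinery as a list was higher in IDM, with 0 of 21 called (camera adjusted p = 5.1e-04, but adjusted p = 0.61 with an estimated correlation).

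At equal depth, 42.3% of the 71 Ei cells held a G2/M transcript (exact 95% interval 30.6% to 54.6%) against 54 of the 74 ENR cells (61.4% to 82.6%), a difference of -30.7 points (-44.6 to -14.7). The same share was 18.5% in EEC-like and 5.56% in enterocyte-like cells of IDE and IDM at the same depth, with whole-cell medians of 3839 and 4635 transcripts in EEC-like and 17091 and 6005 in enterocyte-like cells of IDE and IDM. Free RNA can add to each share. Mki67 stood at 136 CPM of transcripts in Ei and 223 in ENR, a ratio of 0.613 (0.486 to 0.767), and Lgr5 at 246 and 270, a ratio of 0.911 (0.760 to 1.09). Slc12a2, a crypt-base gene, was higher in Ei (ratio 1.58, 1.45 to 1.72). Each of these groups is 1 library, so the intervals hold counting error only. No Dclk1 transcript was found in either, which allows up to 3.17 CPM and 4.49 CPM in ENR and Ei if transcripts are spread evenly over cells.

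**Figure D5:**
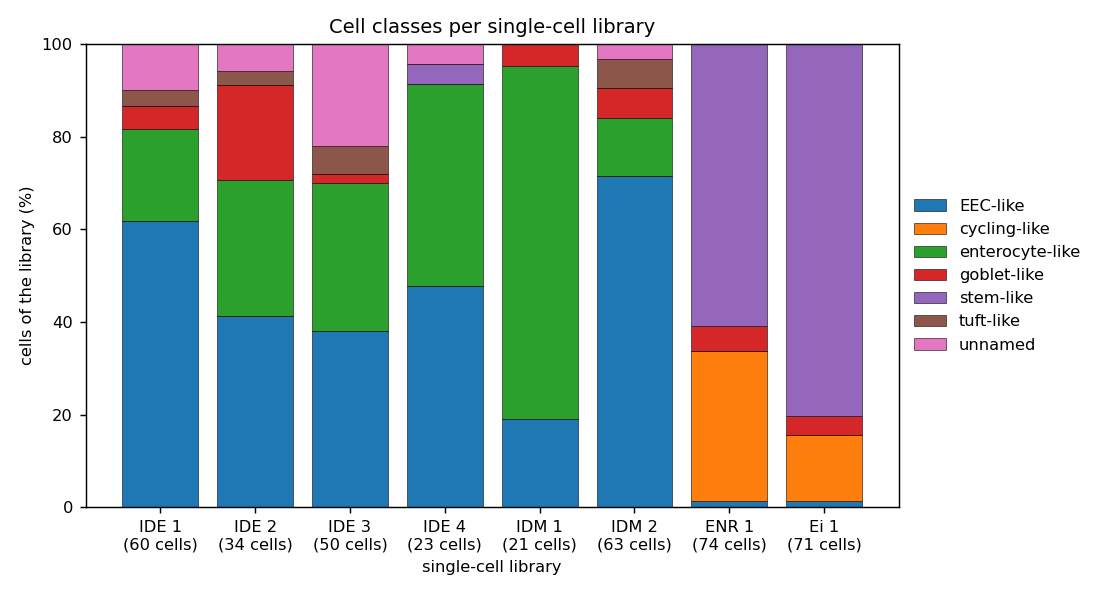
Percent of kept single cells in each named class, stacked by library, with the number of cells under each bar. EEC-like cells made up 19.0% and 71.4% of the 2 IDM libraries and from 38.0% to 61.7% of the 4 IDE libraries.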

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

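The tests of library sets, of sorting as such, of a single mouse line and of the change that the Ptma share can give were chosen after the results were seen, as was the sorted set without Ptma.

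Responses that differed between conditions by a direct test came first. For EGFR inhibition with against without Wnt and Notch inhibition at 96 h, 1149 genes differed, with log2 differences of -4.35 for Muc2, -4.02 for Lyz1, -2.11 for Dclk1, -2.06 for Neurog3, -1.95 for Chga and -1.93 for Mki67 (the last ended without ID replicate 1 or IDE replicate 3, adjusted p up to 0.072). Muc2 and Lyz1 rose in ENR and fell in ID, whereas Chga rose in both and Mki67 fell in both, by different folds. For Mek inhibition 472 genes differed, with -3.63 for Lyz1, -3.03 for Muc2 and -1.82 for Neurog3 (which ended without ENR replicate 2, Mi replicate 1, ID replicate 3 or IDM replicate 3, adjusted p up to 0.16). In 100 splits of the 12 libraries, the real one included, 2 gave as many genes for EGFR inhibition (highest other 1210) and 6 for Mek inhibition (highest other 887). These splits mixed libraries of all 4 conditions. Each other split with as many genes carried the main effect of Wnt and Notch inhibition, from which the real comparison is free, so the splits decide nothing about chance. ID and ENR lie in different library sets, but each inhibitor was compared within its own set, so a set-wide shift cancels in these differences.

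Between Dclk1+ and Lgr5+ cells 130 genes differed in their response to EGFR inhibition, with -2.31 for Dclk1 itself (adjusted p up to 0.067 without Lgr5-GFP Ei replicate 2, Lgr5-GFP ENR replicate 1 or 2, or Lgr5-DTR ENR replicate 2). The count moved with most libraries left out, from 31 without Lgr5-DTR Ei replicate 1 to 418 without Dclk1 ENR replicate 1. In 1 of 14 groups tested for a library far from the others, the percent of stem-like cells in the 4 IDE single-cell libraries, the gap was the whole range (gap over range 1): IDE replicate 4 held 1 stem-like cell of 23 (4.35%) and the others 0. Chance gives such a gap in about 1 in 20 groups of continuous values, a rate that does not hold for 1 cell against 0, so this gap is no sign of a library apart.

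Interferon response genes were high in ID organoids at 96 h, with Ifit1 at 380 CPM (SD 142) against 7.12 CPM (SD 1.87) in ENR. IDE, which lies in the set of ID, had a median log2 change of -3.05 from it, so the set did not share the level of ID. IDE also holds the EGFR inhibitor, which could have lowered a level raised by the set. A difference between library sets therefore cannot be told apart from the treatment. RNA from immune or other non-epithelial cells is argued against by their markers, at 32.9 CPM in ID (SD 3.03), 23.4 CPM in ENR (SD 5.32) and 36.9 CPM in IDM, where the list was low. A single ID library is argued against by 85.7% of the tested genes (6 of 7) having every ID library above every ENR library. For a gene taken alone chance gives 10% for groups apart either way and 5% for this direction. These rates do not apply to the share, since the genes were measured in the same libraries and are not independent. Most of the genes had already been called higher, so the share is not separate evidence of the rise. No biological explanation was tested.

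Ptma took from 12.2% to 22.3% of the counts of the 8 Lgr5+ sorted libraries (mean 17.4%, SD 3.76), and from 2.55% to 3% of the whole organoid controls. In stem-like and cycling-like single cells Ptma was 0.749% of transcripts (136 cells, highest cell 1.37%), below the bound set beforehand against a high level in the cells. Yet the whole organoid controls, at 2.55% or more, also lay above every one of these cells. Bulk counts and single-cell transcripts are different units, so the single cells cannot decide what level Lgr5+ cells hold. Sorting as such is argued against by Dclk1+ libraries, of which the highest held 3.4%. The Ptma shares could change another gene by at most 1.25-fold between Lgr5+ cells and whole organoids. Of the 1238 other called genes 97.7% changed by more, less 2 standard errors (median log2 size 1.61), so most of these changes exceed what the Ptma shares can give. A called gene already lies well beyond its standard error, which favours a high share. Refitting without Ptma gave 1231 calls in place of 1239 and decides nothing, since it moved little in any comparison. What raised Ptma stays open, and no biological explanation was tested beyond its level in single cells.

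Dclk1 and other tuft genes were higher in Lgr5+ cells under EGFR inhibition. A loss of Ptma counts could raise another gene by at most 1.13-fold, and 100% of the 7 called tuft genes rose by more, less 2 standard errors. Their rises exceed what Ptma can give, though choosing called genes favours such a share. A single mouse line is argued against by all 4 Ei libraries lying above all 4 ENR libraries (lowest Ei 16.5 CPM, highest ENR 10.2 CPM). Tuft cells in the sort could not be excluded: of 12 abundant tuft genes, 58.3% lay below 0.5 of the level predicted from the share that Dclk1 implies (3.38%), the other tuft genes implying a median of 1.22% (0.412% to 2.4%), and the bounds set beforehand were 25% and 75%. A sort on Lgr5 reporter signal need not remove them, since Dclk1+ cells held 125 CPM of Lgr5 in Ei (SD 0.431) and 41.2 CPM in ENR (SD 39). A rise of Dclk1 within stem cells may therefore be mixed with a few tuft cells. The 71 single Ei cells held no Dclk1 transcript, an upper limit of 4.49 CPM if transcripts are spread evenly over cells. They came from 1 library whose title names no sort on Lgr5. Bulk counts and single-cell transcripts are also different units, so these cells cannot decide whether stem cells raise Dclk1.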

How the results depend on the processing

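Thinning of the 96 h libraries and the sorted set without Ptma were chosen after seeing the data; the other alternatives were planned. RLE scaling moved 0 of 23 counts by over 1.5 times, a replicate block 0 of 22 bulk counts, removal of Ptma 0 of 6, and no named gene past the threshold changed sign under RLE or DESeq2. With DESeq2 3 of 23 counts moved: 21 genes for IDM against IDE at 6 h, 686 for Dclk1+ cells in Ei and 384 for the Dclk1+ against Lgr5+ response. With no low-count filter 8 moved: 28 (Mi against Ei, 6 h), 56 (ID against ENR, 6 h), 24 (IDM against IDE, 6 h), 766 (Lgr5+ Ei), 781 (Dclk1+ Ei), 484 (Dclk1+ against Lgr5+ response), 7 (Lgr5-DTR against Lgr5-GFP response) and 12 (single cells). With only the groups compared 7 moved: 53 (Mi against Ei, 96 h), 1431 (Lgr5+ Ei), 21 (Dclk1+ Ei), 2812 (Lgr5+ against organoid), 1781 (Dclk1+ against organoid), 63 (Dclk1+ against Lgr5+ response) and 1 (line difference). For these settings the cause was not tested. Thinned to 158135 counts, where fewer genes could be tested (4156), all 9 counts at 96 h were lower: 566 (Ei), 548 (Mi), 44 (Mi against Ei), 1241 (ID), 732 (IDE against ID), 542 (IDM against ID), 144 (IDM against IDE), 447 (EGFR inhibition, difference of responses) and 191 (Mek inhibition). Depth thus limits the counts at 96 h.

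In single cells a replicate block of libraries 1 and 2 gave 1 gene, the G2/M difference was -8.51 points with no thinning, where deeper ENR cells nearly all held a transcript, and -30 and -19.1 points in cells with at least 1000 and 3000 transcripts, within its interval of -44.6 to -14.7. The setting of 3000 kept the same numbers of cells (74 ENR and 71 Ei), so its smaller difference did not come from removing cells. The count of genes between IDM and IDE was 0 in cells with at least 1000 or 3000 transcripts, and the EEC-like share difference -1.59 and -4.73 points there and -1.93 at both other resolutions. Of 469 list tests 209 passed camera with the preset correlation, and 103 with an estimated one.

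With 1 library left out, the counts ranged from 2048 to 2280 (Ei 6 h), 1603 to 1795 (Mi 6 h), 5 to 21 (ID 6 h), 1 to 21 (Mi against Ei 6 h), 1526 to 1833 (IDE 6 h), 1361 to 1649 (IDM 6 h), 0 to 14 (IDM against IDE 6 h), 948 to 1359 (Ei 96 h), 1399 to 1642 (Mi 96 h), 56 to 85 (Mi against Ei 96 h), 2445 to 2773 (ID 96 h), 1372 to 1814 (IDE 96 h), 719 to 936 (IDM 96 h), 105 to 330 (IDM against IDE 96 h), 800 to 1161 and 330 to 421 (differences of responses to EGFR and Mek inhibition), 233 to 295 (Lgr5+ Ei), 310 to 703 (Dclk1+ Ei), 432 to 859 and 1769 to 3082 (Lgr5+ and Dclk1+ against organoid), 31 to 418 (Dclk1+ against Lgr5+), 0 to 1 (line difference) and 0 to 6 (single cells), and the EEC-like share difference from -28.1 to 24.3 points (2.9 without IDE replicate 1), whose direction reversed without IDE replicate 1 or IDM replicate 1.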

Other observations

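The splits of libraries were planned, and the pairs of hormones below were looked at after the data were seen.

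Hormone genes were paired unevenly in the 130 EEC-like single cells, counting a gene as found at 5 or more transcripts. Tac1 and Tph1, both known from enterochromaffin cells, were found together in 47 cells, against 26.8 if independent. Gip, the product of K cells, was found with Tph1 in 0 cells (14.2 if independent) and with Tac1 in 0 (9.8). Cck was found with Gcg in 17 cells (6.28 if independent), with Ghrl in 11 (3.4) and with Tph1 in 5 (18.6). These counts are from cells at their own depth, without thinning, and no test was run on them.

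In 6 libraries there are 10 splits of 3 against 3, too few for a share under 0.05, and in each of the 14 comparisons of that size 1 of the 10 splits, the real one, gave as many genes. The real count and the highest other at 6 h were 2638 and 1 (Ei), 2166 and 0 (Mi), 9 and 0 (Mi against Ei), 21 and 1 (ID), 2109 and 0 (IDE against ID), 1938 and 1 (IDM against ID) and 2 and 1 (IDM against IDE). At 96 h they were 1495 and 0 (Ei), 1894 and 0 (Mi), 88 and 64 (Mi against Ei), 3097 and 0 (ID), 1939 and 1 (IDE against ID), 1100 and 0 (IDM against ID) and 382 and 3 (IDM against IDE). For Lgr5+ cells in Ei, fitted with the line as a term, 1 of 34 splits, the real one, gave as many genes (551 genes, highest other 1). That share is under 0.05, but it is the smallest that 34 splits can give, so chance was not excluded. In all of these comparisons each other split mixed libraries of both treatments, so a true difference would widen the spread within groups. The low counts of the other splits therefore do not show what chance alone would give.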
